A study of Yarrowia lipolytica with 4 samples.

How the data were processed

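Polyadenylated RNA of Yarrowia lipolytica PO1f was measured in 4 libraries, 2 of a ku70 disruption strain (labelled wild type and called the parent here) and 2 of a ku70 disruption strain whose SUR2 gene was replaced by LEU2. Per the labels' protocols the libraries were made with the TruSeq Stranded mRNA kit from total RNA of cells grown to an OD600 of 0.8 at 28 °C. The labels number 2 replicates per strain and do not say that they were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Deposited read counts are whole numbers per gene or per transcript, per the file headers. TPM values, scaled for length and library size, were also deposited by the authors, per the file headers. RPKM values were not used here. The aligner, the counting tool, its strand setting, the genome build and the annotation release are not given in the sources used here. The gene identifiers are of the YALI0 annotation and coordinates are those of the deposited tables. Reads of near-identical genes, of overlapping genes and of genes with an antisense partner can therefore be shared in a way that is not known.

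The data came as 2 tables. The transcript table held 1 library of each strain and the gene table held the other library of each strain, so neither table allows a test alone, and the test planned for the gene table was run on the counts of both tables joined by gene identifier. The column names give the strain but not which replicate number of the labels a library carries, so libraries are named by strain and table. The gene table held 8382 features and 8381 were in both tables, of which 6447 are protein-coding; 1 feature is not used here. No gene had more than 1 transcript. Descriptions were taken from the annotation text for 3817 of the protein-coding genes. Text on hypothetical, unknown or predicted proteins, on proteins without similarity, or with identifiers alone was counted as no description. Gene names are those of the descriptions, most of them given by similarity to other species. The supplied reference table of gene symbols was for another assembly and was not used. One gene of the preset set of strain markers is not reported here. The counts of each pair of libraries of a strain differed by far more than sampling noise (chi-square per degree of freedom of 144.8 for the parent pair and 292.8 for the deletion pair), so each library was counted as 1 replicate. The libraries of a pair stood in different tables, so differences between the tables are part of these values. They do not show that the libraries were separate cultures. Protein-coding genes held 99.985% to 99.992% of the counts, the most abundant gene, YALI0_C09141g, 1.785% to 3.36% and the 10 most abundant genes 6.28% to 9.687%. Totals ran from 8765729 to 16698719 counts, and 3 counts, the limit that a count of 0 allows, corresponded to 0.1797 to 0.3422 CPM of a library. Such floors cover counting error only.

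Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by strain left 6051 genes. Trimmed mean (TMM) factors were 1.034 and 0.846 for the parent and 1.025 and 1.115 for the deletion libraries of the transcript and the gene table. The quasi-likelihood test with strain as the only term was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All tests were two-sided. The common dispersion was 0.1424. CPM were computed from library totals scaled by those factors. Standard errors of log2 fold changes were taken from the fold change and its F value, and none is given for a gene without reads in a group, whose change is given as a lower bound against a floor of 3 counts over the group. The median log2 fold change over all tested genes was 0.03. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, over 28 lists of at least 4 tested members. A gene joined a list by a symbol, a phrase of its annotation or its identifier, and 76 matches that the annotation contradicted were removed without looking at values. The pattern for cytosolic ribosomal proteins missed most of them, and a wider match was added after the tables were opened. Where a list's genes are compared with other genes, genes are not independent replicates. The 2 tables were also set side by side by TPM with a pseudocount of 1, a mean of at least 10 and a log2 ratio of at least 1, without a test.

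The strain groups, the tests, the gene lists, the alternatives and the rule for naming genes were chosen before the data were examined. The rule names the strain markers, each tested sphingolipid gene, the 10 largest rises and 10 largest falls among described genes past the threshold whose groups do not overlap and whose higher mean is at least 10 CPM, and the 4 genes of smallest p in each list that passed or held at least 3 genes past the threshold. Where fewer than 10 fell, the next by unadjusted p were named as not passing. Settings chosen in advance for comparison were DESeq2 1.42.0, relative log expression (RLE) factors, no filter, limma on log2(TPM + 1), fry, an estimated correlation within lists and leaving out each library in turn. Chosen after seeing the data were a fit with the deposited table as a term and counts thinned to the total of the smallest library. With 1 library left in a strain, that library was assumed to vary like those of the other strain.

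The steps were tested on simulated counts drawn from the means and sizes of these libraries for the deletion strain against the parent, over 6002 tested genes. Of 50 genes above 10 CPM changed at each fold, edgeR called 12% at 2-fold, 70% at 4-fold, 100% at 8-fold and 100% at 16-fold, with 12 false calls among 5802 unchanged genes. A simulated list raised 2-fold had an adjusted p of 2.56e-10 with camera's preset correlation, and 0 random lists were called. The estimated correlation and fry were not tried on it. Simulated genes varied independently of each other, so this does not test camera on lists whose genes vary together. Numerical work also used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.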

Results

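Messenger RNA was sequenced from 2 strains of Yarrowia lipolytica, an oil-storing yeast that grows as single cells or as hyphae. The aim was to compare gene expression with and without SUR2, the C4-hydroxylase of sphingoid bases. Both strains were made in PO1f, a laboratory strain that needs added leucine and uracil. Both also carried a disruption of KU70, which encodes a subunit of the complex that joins broken DNA ends. The strain with KU70 alone disrupted is called the parent here, and in the other strain SUR2 was replaced by LEU2. Cells were harvested at an OD600 of 0.8 from rich YPD medium at 28 °C, and each strain had 2 libraries. A table of transcripts and a table of genes each held 1 library of each strain, so libraries are named below by strain and table. The totals were 16585818 and 16698719 counts for the parent and the sur2 deletion library of the transcript table. They were 13972149 and 8765729 counts for those of the gene table. Across genes, which are not independent replicates, the log2 CPM, counts scaled to library size, of the parent libraries correlated at r = 0.952 and those of the deletion libraries at r = 0.914. Between strains r was 0.93 within the transcript table, 0.881 within the gene table, and 0.925 and 0.852 across tables. Values after ± are standard deviations over the 2 libraries for CPM and standard errors for log2 fold changes.

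SUR2 (YALI0_E17347g, chromosome E, 2049611 to 2050672) was read in both parent libraries and in neither deletion library. The parent libraries held 1402 and 1319 reads of it (96.7 ± 21.1 CPM, n = 2). The deletion libraries held 0 and 0, a level at least 756-fold lower with a floor of 3 counts over the group (adjusted p = 0.00438, edgeR). Reads of LEU2 (YALI0_C00407g, chromosome C, 46411 to 46866), the leucine synthesis gene used as the marker, numbered 1532 and 2400 in the parent and 1040 and 1528 in the deletion strain. Its log2 fold change of -0.43 ± 0.55 did not pass the test (adjusted p = 0.845). The parent, in which SUR2 was not replaced by LEU2, had reads here too, so these reads do not report the inserted marker alone. KU70 (YALI0_C08701g, chromosome C, 1180709 to 1182466), labelled as disrupted in both strains, had 89 and 23 reads in the parent and 52 and 14 in the deletion strain (log2 fold change -0.67 ± 0.76, adjusted p = 0.821). With the transcript table's parent library left out the adjusted p of SUR2 was 0.469, and with the gene table's parent library left out it was 0.432, although its reads stayed at 0 in both deletion libraries. Without either deletion library it was 1.8e-23 or 1.41e-24.

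The comparison of the deletion strain with its parent asks which transcripts differ when SUR2 is replaced by LEU2. Loss of SUR2 and gain of the LEU2 marker cannot be told apart in it. Any other difference between the strains is part of it too, and genes at chromosome ends given below had reads in 1 strain only. The gene that rose most among those named by the preset rule was YALI0_B17204g (chromosome B, 2260004 to 2260660), annotated as the sterol C-8 isomerase ERG2, from 1.57 ± 0.652 to 365 ± 200 CPM, or 235-fold (log2 fold change 7.87 ± 0.67, adjusted p = 0.00438). The predicted potassium transporter gene YALI0_C10311g rose from 0.201 ± 0.0454 CPM, with 4 and 2 parent reads, to 31.2 ± 21.2 CPM (adjusted p = 0.0144). The ABC transporter gene YALI0_B12980g rose 42-fold, from 4.63 ± 1.1 to 194 ± 64.3 CPM (adjusted p = 0.00438). YALI0_F07062g, annotated as the polyamine transporter TPO1, rose 30.9-fold, from 4.86 ± 1.26 to 150 ± 112 CPM (adjusted p = 0.0173). The aldo/keto reductase gene YALI0_B07117g, annotated as GCY1, rose 49.7-fold to 244 ± 70.9 CPM (adjusted p = 0.00438). Genes annotated as the cell wall proteins PIR1 (YALI0_B20306g) and CWP1 (YALI0_F18282g) rose 33.1-fold and 39.6-fold, to 422 ± 342 and 121 ± 107 CPM (adjusted p = 0.0204 and 0.0226). The dihydroxyacetone kinase gene YALI0_F01606g rose 50.6-fold (adjusted p = 0.017). YALI0_F01650g, annotated as the peroxisomal dienoyl-CoA reductase SPS19, rose 33.6-fold (adjusted p = 0.0147). The ADP/ATP carrier gene YALI0_D08228g rose from 28.3 ± 3.58 to 1020 ± 1090 CPM (adjusted p = 0.042). The deletion libraries held 4265 and 17494 of its reads. Without the gene table's deletion library the log2 fold changes of YALI0_B17204g, YALI0_C10311g, YALI0_F01606g, TPO1, PIR1, CWP1 and the ADP/ATP carrier gene were 7.17, 6.25, 4.80, 3.87, 3.82, 3.89 and 3.14, against 7.87, 7.18, 5.66, 4.95, 5.05, 5.31 and 5.17 with all libraries. Without that of the transcript table those of TPO1, PIR1, CWP1 and the carrier gene were 5.56, 5.70, 6.0 and 5.98, and without the gene table's parent library that of SPS19 was 5.84, against 5.07. With limma on TPM those of YALI0_B12980g, YALI0_C10311g and YALI0_F01606g were 4.32, 3.13 and 3.27, on a scale that understates changes of low genes, and with the table as a term that of the carrier gene was 4.57.

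**Figure D1:**
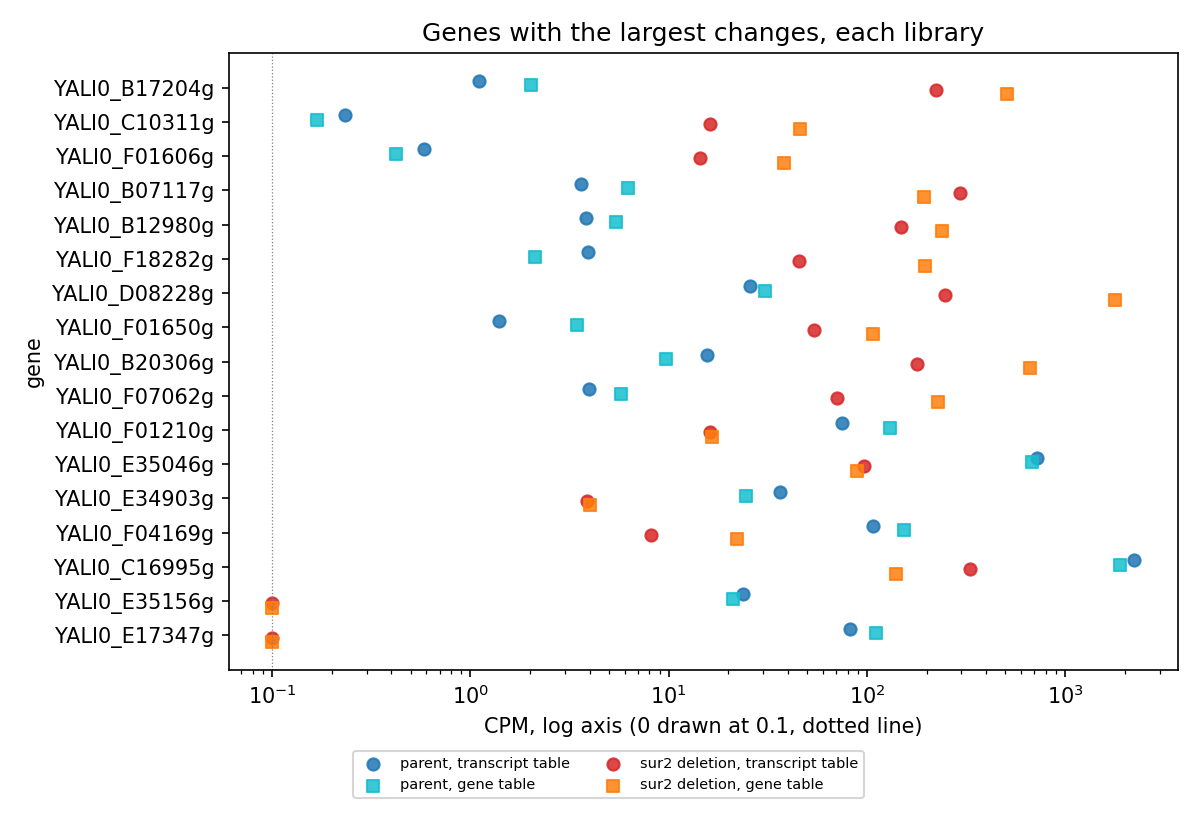
CPM of each library on a log axis for the 17 genes with the largest rises and falls that passed the test and were named by the preset rule. Circles are the libraries of the transcript table and squares those of the gene table, blue for the parent and red or orange for the sur2 deletion. Both deletion libraries lie on the same side of both parent libraries for each gene, as the rule required. SUR2 (YALI0_E17347g) and YALI0_E35156g are at 0 in both deletion libraries, drawn at 0.1.

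Of the genes that fell, YALI0_C16995g, encoding the gluconeogenic enzyme phosphoenolpyruvate carboxykinase PCK1, dropped 8.72-fold, from 2061 ± 246 to 236 ± 137 CPM (log2 fold change -3.12 ± 0.56, adjusted p = 0.0433). Glycogen phosphorylase GPH1 (YALI0_F04169g) fell 8.68-fold, from 131 ± 32.4 to 15.1 ± 9.85 CPM (adjusted p = 0.0385). The predicted water channel YALI0_F01210g fell 6.29-fold, from 103 ± 39.6 to 16.4 ± 0.169 CPM (adjusted p = 0.0272). YALI0_E35156g, annotated as the urea amidolyase DUR1,2, had 405 and 251 reads in the parent and 0 and 0 in the deletion strain, at least 182-fold fewer (adjusted p = 0.011). Near it on the right end of chromosome E, the HSP70 gene YALI0_E35046g fell 7.52-fold, from 700 ± 29.4 to 93 ± 5.02 CPM (adjusted p = 0.0204). YALI0_E34903g, farther in, annotated as the transporter ESBP6, fell 7.78-fold (adjusted p = 0.0293). Within this end 4 genes with reads in both parent libraries had 0 reads in both deletion libraries. They were YALI0_E35156g and YALI0_E34947g, YALI0_E35024g and YALI0_E35112g, the last 3 of which were singled out after their values were seen. The next largest decreases among genes chosen by the same rule did not pass. The 3-isopropylmalate dehydratase gene (YALI0_B01364g) had a log2 fold change of -2.61 ± 0.51 (adjusted p = 0.0602). The predicted transporter gene YALI0_F21109g had one of -2.12 ± 0.44 (adjusted p = 0.0735) and the ABC transporter gene PDR15 (YALI0_B02544g) one of -2.49 ± 0.52 (adjusted p = 0.079). With DESeq2 all 3 passed (adjusted p = 3.15e-06, 3.3e-04 and 2.14e-04), and the first also passed without the filter, with limma on TPM and with the table as a term (0.0475, 0.0108 and 0.044). Over all alternatives their adjusted p ran from 2.64e-06 to 0.664, from 2.15e-04 to 0.712 and from 5.98e-06 to 0.793. With limma on TPM YALI0_E35156g and YALI0_E34903g did not pass (adjusted p = 0.134 and 0.0706, with ranges over the alternatives of 1.51e-13 to 0.469 and 1.93e-06 to 0.484). The log2 fold change of GPH1 was -4.0 without the gene table's deletion library and that of PCK1 -3.89 without the transcript table's, against -3.12 for both with all libraries.

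**Figure D2:**
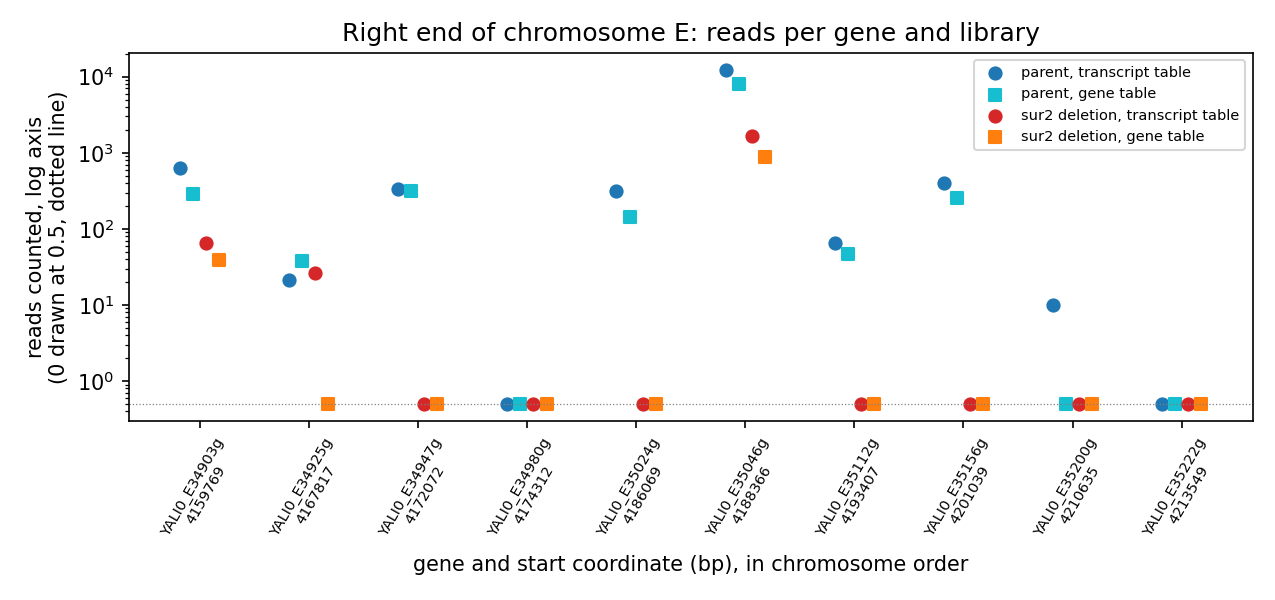
Reads counted per library, on a log axis, for the last 10 genes at the right end of chromosome E in chromosome order, with 0 drawn at 0.5. Circles are the transcript table and squares the gene table, blue for the parent and red or orange for the deletion strain. YALI0_E34947g, YALI0_E35024g, YALI0_E35112g and YALI0_E35156g lie at 0 in both deletion libraries, while YALI0_E35046g keeps 1653 and 874 reads there.

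In all, 75 of the 6051 genes tested passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 60 higher and 15 lower in the deletion strain. Each of them also passed the preset size threshold of 1 on the log2 scale, and the smallest change was 2.04. For all 75 genes the 2 groups did not overlap and the sign was shared by both tables. The genes were chosen by a test on these same libraries, and a shared sign follows from groups that do not overlap. Neither is therefore a separate check of the calls. Over all tested genes 42.3% had groups that did not overlap, against 33.3% by chance. For 31 of the 75 genes, of which 24 were higher, the annotation held no description beyond identifiers or a hypothetical or unknown protein. The 15 lower genes include the deleted SUR2 itself. They also include YALI0_E34903g, YALI0_E34947g, YALI0_E35024g, YALI0_E35046g, YALI0_E35112g and YALI0_E35156g, all among the last 10 genes of chromosome E. The 60 higher genes include YALI0_B00110g and YALI0_B00132g, at the left end of chromosome B, with 0 reads in both parent libraries. Neighbours at either end may not be separate changes. The same counts gave 386 genes with DESeq2, and the TPM values gave 219 with limma. With the deposited table as a term edgeR called 145 genes, 112 higher and 33 lower, all 75 among them. When the parent library of the transcript table or of the gene table was left out, edgeR called 0 genes, with 414 and 361 at an unadjusted p under 0.05. Without the deletion library of the transcript table or of the gene table it called 685 and 204.

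Among the preset list of sphingolipid genes, SUR2 was the only one of 15 tested members that passed edgeR's test over all genes, and 0 rose by that test. Adjusted over the list alone, 1 was higher and 1 lower. The higher one was the ceramide glucosyltransferase gene YALI0_B09669g, whose enzyme makes glucosylceramide, at 22.2 ± 12 CPM in the parent and 119 ± 49 CPM in the deletion strain (log2 fold change 2.42 ± 0.52, adjusted p = 0.0822 over all genes). The alkaline dihydroceramidase YDC1 (YALI0_D20262g) had a log2 fold change of 1.79 ± 0.55 (adjusted p = 0.22). With DESeq2 both passed (adjusted p = 2.64e-04 and 0.0329), and the first also with limma on TPM (0.00939); over all alternatives their adjusted p ran from 1.57e-06 to 0.71 and from 3.27e-05 to 0.809. Without the gene table's parent library the log2 fold change of the first was 3.11, and that of YDC1 was 0.89 without the gene table's deletion library. A gene related to acid sphingomyelinase (YALI0_E31581g) had one of -1.61 ± 0.70 (adjusted p = 0.404). It was -2.48 and passed without the transcript table's deletion library (adjusted p = 0.0215, in a range over the alternatives of 0.0215 to 0.903) and -0.88 without the gene table's parent library. The ceramide hydroxylase SCS7 (YALI0_F12749g) and the inositol phosphorylceramide synthase AUR1 (YALI0_E16434g) had log2 fold changes of 0.83 ± 0.39 and 0.77 ± 0.39. Those of the long-chain base kinase LCB5 (YALI0_B11154g) and the 3-ketosphinganine reductase TSC10 (YALI0_B17688g) were 0.60 ± 0.37 and 0.52 ± 0.36, and that of another sphingomyelinase-related gene (YALI0_F12595g) was 0.98 ± 0.67, or 0.18 without the transcript table's deletion library. The serine palmitoyltransferase subunit LCB2 (YALI0_F15345g), ceramide synthase LAC1 (YALI0_F06424g), ORM1 (YALI0_B18150g), ISC1 (YALI0_D18458g), the elongase YALI0_B20196g and the delta 8 sphingolipid desaturase YALI0_E21131g lay between -0.27 and 0.35 on the log2 scale, none past the test. The list's median log2 fold change was 0.35 and its mean -0.47, which holds the fitted value of SUR2. The list, SUR2 included, did not differ from the other genes (camera adjusted p = 0.597, upward, while fry's direction was downward). No test was run without the deleted SUR2, so these results cannot show whether its other members shifted together. For 9 of the 15 genes the groups did not overlap with the deletion strain higher, and for 2, SUR2 among them, with it lower.

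Of the 28 preset lists, 9 differed from the other genes with camera's preset correlation, 6 lower and 3 higher in the deletion strain, and 0 did with an estimated correlation (adjusted p = 0.853 for each of the 9). The estimated correlation rests on the spread of 2 libraries per strain and has little power here. It was not tried on simulated lists, so its 0 cannot show that a list is unchanged. The preset correlation may be too low for genes that vary together, so neither setting decides. With the preset correlation ribosomal protein and oxidative phosphorylation genes were lower as groups, though 0 of their members passed edgeR's test singly. With DESeq2 6 cytosolic ribosomal protein genes and 1 oxidative phosphorylation gene were lower and 0 mitochondrial ribosomal protein genes passed, and with limma on TPM 0 did in each list. At an unadjusted p under 0.05 edgeR gave 12, 15 and 4. The 20 cytosolic ribosomal protein genes tested had a median log2 fold change of -1.21 (adjusted p = 2.22e-11, and adjusted p = 0.853 with an estimated correlation). For all 20 the groups did not overlap, against 42.3% of all tested genes and 33.3% by chance, but genes of 1 list are not independent of each other. Those with the smallest p included S28 (YALI0_C05148g, -1.69 ± 0.43) and S23 (YALI0_A20746g, -1.57 ± 0.48), which ran from -2.30 to -1.21 and from -1.93 to -1.10 over the alternatives. The 55 oxidative phosphorylation genes had a median of -0.92 (adjusted p = 6.31e-14, and adjusted p = 0.853 with an estimated correlation). Cytochrome c CYC1 (YALI0_D09273g) was at -1.77 ± 0.60, COX8 (YALI0_F04103g) at -1.24 ± 0.39, and NADH dehydrogenase NDH64 (YALI0_E05599g) at 1.57 ± 0.54. Without the transcript table's deletion library these were -2.88, -1.64 and 2.16 and passed (adjusted p = 2.76e-04, 0.0188 and 1.68e-04), while without the gene table's CYC1 was at -1.15 and NDH64 at 0.54. Over all alternatives the adjusted p of the 3 ran from 2.76e-04 to 0.847, from 0.0188 to 0.825 and from 1.68e-04 to 0.9. The 44 mitochondrial ribosomal proteins had a median of -0.61 (adjusted p = 1.1e-07, and adjusted p = 0.853 with an estimated correlation). These medians were larger in the gene table, at -2.0 for cytosolic ribosomal proteins, -1.68 for oxidative phosphorylation and -1.05 for mitochondrial ribosomal proteins, than in the transcript table, at -0.47, -0.30 and -0.24.

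The 11 genes of leucine, valine and isoleucine synthesis had a median of -0.68 (adjusted p = 0.0014, and adjusted p = 0.853 with an estimated correlation). The median was -0.39 in the transcript table and -1.25 in the gene table. None of them passed over all genes with edgeR, 3 were lower when adjusted over the list alone, and 3 were at an unadjusted p under 0.05. With DESeq2 and limma on TPM 3 and 2 were lower. The 3 with edgeR were the 3-isopropylmalate dehydratase gene YALI0_B01364g given above and the aminotransferase genes BAT1 (YALI0_D01265g) and TWT2 (YALI0_F19910g). BAT1 was at 972 ± 252 CPM in the parent and 226 ± 92.5 CPM in the deletion strain (log2 fold change -2.11, from -2.61 to -1.73 over the alternatives). TWT2 had a log2 fold change of -1.69 ± 0.52, and the acetolactate synthase subunit gene YALI0_C09636g, next by p, one of -0.84 ± 0.43. The strains also differ by the LEU2 marker, in a background that needs added leucine. For this list, too, the marker and the loss of SUR2 cannot be told apart. The 25 heat shock and chaperone genes had a median of -0.53 (adjusted p = 0.00827, and adjusted p = 0.853 with an estimated correlation), or -0.27 in the transcript table and -1.0 in the gene table. With edgeR 1 of them rose, the 12 kDa heat shock protein gene YALI0_D20526g (log2 fold change 3.86 ± 0.69, adjusted p = 0.042, or 4.96 and 3.24 without the parent library of the transcript and of the gene table). The 1 that fell was the HSP70 gene YALI0_E35046g of the chromosome E end. Adjusted over the list alone 1 was higher and 2 lower. With DESeq2 2 were higher and 3 lower, and with limma on TPM 1 was higher and 1 lower. The disaggregase HSP104 (YALI0_E27962g) was at -1.62 ± 0.42 (adjusted p = 0.146, or 0.00146 to 0.829 over the alternatives). The 18 genes of the TCA and glyoxylate cycles had a median of -0.32 (adjusted p = 0.0383, and adjusted p = 0.853 with an estimated correlation), or -0.26 and -0.23 in the transcript and the gene table. With edgeR, DESeq2 and limma on TPM 0 of them passed, and 2 had an unadjusted p under 0.05 with edgeR. Isocitrate dehydrogenase IDP2 (YALI0_F04095g) was at -1.06 ± 0.43 and malate synthase (YALI0_D19140g) at 1.88 ± 0.74. The latter rested on the gene table's deletion library, without which it was 0.04, and it was 2.67 without the transcript table's (adjusted p = 0.999 and 2.84e-06, the range over the alternatives).

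The 38 cell wall genes had a median of 0.39 (adjusted p = 1.07e-04, and adjusted p = 0.853 with an estimated correlation), or 0.29 in the transcript table and 1.05 in the gene table. With edgeR 4 of them rose and 0 fell, and 6 were higher when adjusted over the list alone. With DESeq2 7 were higher and 0 lower, as with limma on TPM. Besides PIR1 and CWP1, a further CWP1 gene (YALI0_E11517g) rose 18.5-fold (adjusted p = 0.0378), a log2 fold change of 4.21 that was 4.91 and 2.76 without the deletion library of the transcript and of the gene table. The mannoprotein gene TIR3 (YALI0_B14795g) rose 6.62-fold, from 124 ± 50.7 to 824 ± 146 CPM (adjusted p = 0.042). The 40 secreted proteases and lipases had a median of 0.46 (adjusted p = 0.0316, and adjusted p = 0.853 with an estimated correlation), or 0.64 and 0.32 in the transcript and the gene table. The acid extracellular protease gene AXP1 (YALI0_E33363g) was the 1 that rose with edgeR, by 16.1-fold (adjusted p = 0.0269), a log2 fold change of 4.01 that was 3.35 without the gene table's deletion library. Adjusted over the list alone 3 were higher and 1 lower. With DESeq2 4 were higher and 1 lower, as with limma on TPM. The triacylglycerol lipase gene YALI0_A20350g was at 776 ± 138 CPM in the parent and 159 ± 68.6 CPM in the deletion strain (log2 fold change -2.29 ± 0.48, edgeR adjusted p = 0.0811). The 23 genes of autophagy and vacuolar proteolysis had a median of 0.94 (adjusted p = 0.00827, and adjusted p = 0.853 with an estimated correlation). With edgeR 0 of them passed and 4 had an unadjusted p under 0.05, while 3 were higher with DESeq2 and 0 passed with limma on TPM. That median was 1.20 in the gene table and 0.09 in the transcript table. The ABC and multidrug transporter list held 3 genes that rose with edgeR among 40 tested. They were YALI0_B12980g, YALI0_F07062g and the glutathione conjugate transporter YCF1 (YALI0_F12089g, 9.19-fold, adjusted p = 0.017). Adjusted over the list alone 5 were higher and 1 lower, but the list as a whole did not pass (adjusted p = 0.136). With DESeq2 5 of its genes were higher and 1 lower, and with limma on TPM 5 were higher and 0 lower.

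With the correlation estimated per list, and with fry, 0 of the 28 lists passed and 0 had an unadjusted p under 0.05, the smallest being 0.0961 and 0.0532. Fry tests whether the genes of a list move one way and does not compare them with other genes. The limit given above for the estimated correlation holds here too. Without the gene table's deletion library the adjusted p of the autophagy list was 0.556. Without the transcript table's deletion library those of the TCA and protease lists were 0.564 and 0.799, and without the gene table's parent library those of the TCA, protease, branched-chain amino acid, cell wall and autophagy lists were 0.514, 0.119, 0.119, 0.0657 and 0.0657. Over all alternatives the adjusted p of the 9 lists ran from 2.86e-18 to 0.853.

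**Figure D3:**
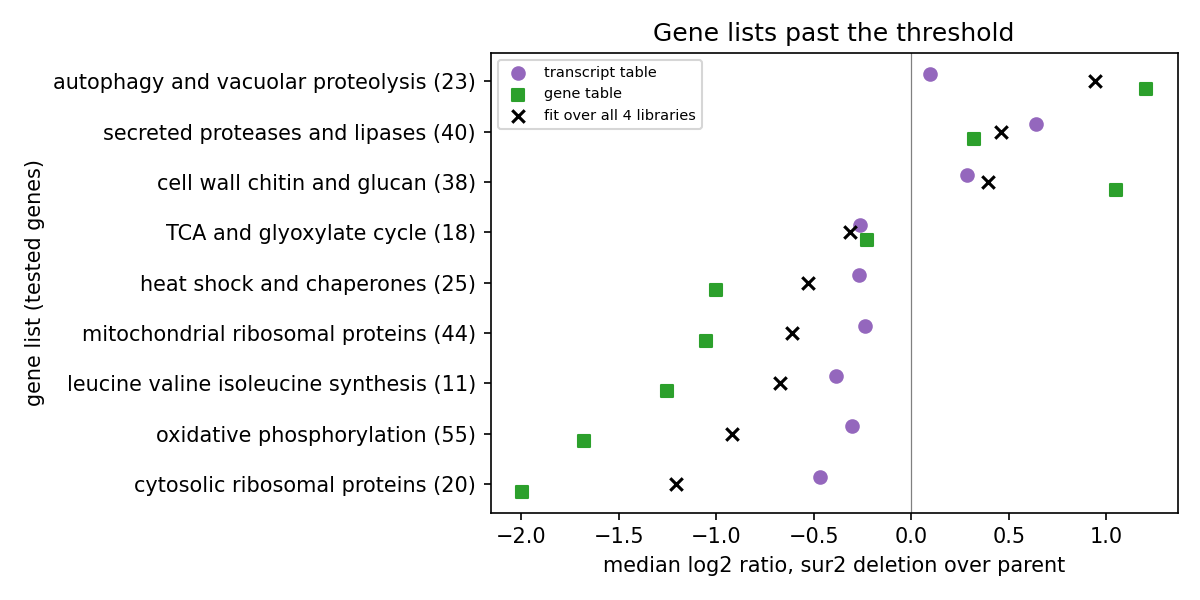
Median log2 ratio of the sur2 deletion over the parent for the 9 gene lists past the threshold with a preset correlation, from the library pair of each table (circles and squares) and from the fit over all 4 libraries (crosses), with the number of tested genes in brackets. The medians of the lists for cytosolic ribosomal proteins, oxidative phosphorylation and mitochondrial ribosomal proteins lie below 0 in both tables, at -0.47 and -2.0 for the cytosolic ribosomal proteins.

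The other 17 lists did not pass. In lipid metabolism, ergosterol synthesis had 1 gene that rose, YALI0_B17204g, and 0 that fell of 22 (adjusted p = 0.123), with a median of -0.38 and a mean of 0.14. The other gene annotated as ERG2, YALI0_E32065g, named after its values were seen, was at 233 ± 88.8 CPM in the parent and 131 ± 27.4 CPM in the deletion strain (log2 fold change -0.83 ± 0.42, adjusted p = 0.492). With edgeR none of the members passed over all genes in very-long-chain fatty acid elongation (4 tested, adjusted p = 0.356), fatty acid synthesis and desaturation (7, 0.356), triacylglycerol synthesis and lipolysis (15, 0.816), peroxisomal beta-oxidation (14, 0.897), alkane cytochrome P450s (12, 0.721) or phospholipid synthesis (15, 0.996). Adjusted over the list alone with edgeR, 1 triacylglycerol gene was lower and 1 ergosterol gene higher, and 0 passed in the other 5 of these lists. With DESeq2 1 triacylglycerol gene and 1 beta-oxidation gene were lower and 1 phospholipid gene was higher. With limma on TPM 1 triacylglycerol gene was lower. Glycolysis and gluconeogenesis had 1 gene that fell with edgeR of 16, PCK1, also when adjusted over the list alone (adjusted p = 0.597 for the list). With DESeq2 1 was higher and 1 lower, and with limma on TPM 1 was lower. Iron uptake had 1 gene that fell with edgeR of 24, the predicted ferric reductase YALI0_E35112g of the chromosome E end, with 4 higher and 1 lower when adjusted over the list alone (adjusted p = 0.0795 for the list). With DESeq2 5 were higher and 1 lower, and with limma on TPM 3 were higher and 0 lower. Amino acid and peptide transport had 0 of 33 past edgeR's test over all genes and 3 higher and 1 lower when adjusted over the list alone (adjusted p = 0.308 for the list). With DESeq2 3 were higher and 2 lower, and with limma on TPM 1 was higher. Hexose transport had 0 of 16 past edgeR's test over all genes and 1 higher when adjusted over the list alone (adjusted p = 0.523 for the list). With DESeq2 1 was higher and 1 lower, and with limma on TPM 1 was higher. The adjusted p was 0.0765 for the proteasome (37 tested), 0.246 for regulators of hyphal growth (15), 0.403 for the unfolded protein response (9). It was 0.721 for histones and DNA replication (20), 0.731 for ribosome biogenesis (39) and 0.825 for oxidative stress (25). In each of these 6 lists 0 members passed with edgeR, over all genes or adjusted over the list alone. With DESeq2 2 oxidative stress genes, 1 ribosome biogenesis gene and 1 regulator of hyphal growth were higher. With limma on TPM 1 oxidative stress gene and 1 proteasome gene were higher. The ribosome biogenesis list had medians of opposite sign in the 2 tables, 0.90 in the transcript table and -0.73 in the gene table.

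Set side by side, the tables gave different numbers of genes beyond the preset 2-fold rule on TPM + 1 with a mean of at least 10, for which no test was possible with 1 library per strain. Of 4859 genes in the transcript table, 470 were higher and 168 lower in the deletion strain. Of 4801 in the gene table, 1735 were higher and 190 lower. The median log2 ratios were 0.05 and 0.73. Relative to its own median, the transcript table had 436 genes higher and 186 lower, and the gene table had 634 higher and 535 lower. Over the 4645 genes in both, the log2 ratios of the tables correlated at Pearson's r = 0.42 and Spearman's rho = 0.241 across genes. After each table's median was subtracted, 158 genes were higher in both tables and 78 lower in both, where independent tables would give 47.7 and 17.8. Another 25 went opposite ways.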

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

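Fits with the deposited table as a term, with thinned counts and with the wider ribosomal list were chosen only after the results were seen. Against 75 genes past the threshold, and as many with the size limit of 1 on the log2 scale, DESeq2 gave 386 (262 higher, 124 lower), limma on TPM 219 and the table term 145, while RLE factors gave 77, no filter 96 and thinned counts 78, of which 74 were shared. Leaving out 1 library gave 0 to 685: 0 without the parent library of the transcript table and 0 without that of the gene table (414 and 361 genes at an unadjusted p under 0.05), 204 without the gene table's deletion library and 685 without the transcript table's. With a library gone the spread is that of the strain that keeps 2 libraries, and the deletion pair differed more than the parent pair (chi-square per degree of freedom 292.8 against 144.8). For the other changes the cause was not tested. Of the 70 named genes 22 passed, 42 did so with DESeq2, and 0 to 45 with a library left out, 0 of them without either parent library and 45 without the transcript table's deletion library. Without a library the fitted log2 fold change of SUR2, which depends on the prior count, was -13.54 to -13.23, and its adjusted p was 0.469 and 0.432 without the parent library of the transcript and the gene table. That of LEU2 was -1.27 to 0.28 (0.09 without the transcript table's deletion library, 0.28 without the gene table's parent library), and that of KU70 -1.32 to 0.17 (0.17 without the transcript table's parent library). Among sphingolipid genes, 3 with small decreases changed sign with limma on TPM: YALI0_B20196g to 0.17, YALI0_E21131g to 0.003 and YALI0_F15345g to 0.30. Without a library they ran from -0.65 to 0.17, from -1.06 to 0.24 and from -0.39 to 0.15 (0.01 for YALI0_F15345g without the gene table's deletion library). Of the 22, the fold change on the linear scale moved by over 1.5 times in 8 with limma on TPM, 2 with DESeq2, 2 with thinned counts, 1 with the table term, 6 and 10 without the deletion library of the transcript and of the gene table, and 1 and 2 without the parent libraries. With limma on TPM 2 of them no longer passed, the urea amidolyase gene YALI0_E35156g and YALI0_E34903g. The cause was not tested. The TPM were not centred in that fit, and their median log2 ratios were 0.05 and 0.73 in the transcript and the gene table. Its log2 fold changes, with the 3 changes of sign above, therefore include an upward shift. That of ISC1 went from 0.07 to 0.46. Of the 28 lists, 9 passed, and 0 did with an estimated correlation or with fry, which compares no list with other genes; 9 passed with RLE factors, 9 with the table term (TCA lost at 0.0659), 8 with thinned counts (proteases lost at 0.0657) and 7 to 11 with a library left out. The wider ribosomal list, 79 genes with a median of -1.18 and 0 past the test, had camera p = 7.48e-30 and p = 0.205 with an estimated correlation. No paired analysis was possible because the columns carry no replicate number that matches the labels, so the labels' numbers could not be used as pairs. The fit with the table as a term, with 145 genes, blocks the libraries by table instead. A pseudocount of 0.1 and a filter on low values were planned for normalized values alone and were not run, and summing transcripts per gene moved nothing because no gene had more than 1. Changes of 2-fold were mostly beyond this depth and number of libraries, since 12% of such simulated genes were called.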

Other observations

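The genes and families in this part were chosen after their values were seen, apart from the preset lists and the genes the report already named by rule. All tests of the explanations weighed here were chosen after the results were seen, except those of the ERG2 neighbours and of length- and level-matched lists. Of 7 tested genes annotated as GCY1-like aldo/keto reductases, a family that reduces aldehydes and ketones with NADPH, 4 rose and 0 fell. Besides YALI0_B07117g, YALI0_A15906g rose 14.7-fold, YALI0_D04092g 11.7-fold and YALI0_B21780g 10.4-fold (edgeR adjusted p = 0.0176, 0.0393 and 0.018), whereas YALI0_E18348g, YALI0_C13508g and YALI0_F18590g had log2 fold changes of 3.34 ± 0.90, 1.41 ± 0.46 and 0.42 ± 0.51 that did not pass (adjusted p = 0.164, 0.245 and 0.841). The dihydroxyacetone kinase and dienoyl-CoA reductase genes flank YALI0_F01628g on chromosome F, which has no description and rose 66.6-fold (adjusted p = 0.0147). The acid trehalase gene YALI0_E07744g, ATH1, rose from 46 ± 5.04 to 1222 ± 670 CPM (adjusted p = 0.0147), and the sulfate assimilation gene MET16 (YALI0_B08140g) rose 13-fold to 296 ± 116 CPM (adjusted p = 0.018). The ABC transporter gene YALI0_C20265g, annotated as YlABC2, rose 10.9-fold (adjusted p = 0.0362), a gene annotated as the flocculin FLO1 (YALI0_B21450g) rose 16.1-fold (adjusted p = 0.0144), and the predicted vacuolar calcium exchanger VCX1 (YALI0_B09273g) rose 4.12-fold (adjusted p = 0.0367). Without the gene table's deletion library the log2 fold changes of YALI0_A15906g, YALI0_F01628g, ATH1 and YALI0_C20265g were 3.15, 5.40, 4.02 and 2.64, against 3.88, 6.06, 4.73 and 3.45 with all libraries. Without the gene table's parent library those of YALI0_D04092g and YALI0_F01628g were 4.67 and 6.81, and without the transcript table's parent library they were 2.88 and 5.45, against 3.55 and 6.06. Each of these calls, like all others, was lost when either parent library was left out.

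More CPM, by over 8-fold, stood in the transcript table than in the gene table for 19 genes in both strains, and the reverse held for 0 genes. YALI0_B23496g had 11586 and 15869 reads in the parent and deletion library of the transcript table and 2 and 0 in the gene table, and YALI0_A21351g had 1696 and 1959 against 0 and 0.

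At the right end of chromosome E, 4 of the 7 genes with reads in both parent libraries, among the last 10, had 0 reads in both deletion libraries: YALI0_E34947g (335 and 318 parent reads), YALI0_E35024g (319 and 143), YALI0_E35112g (66 and 47) and YALI0_E35156g (405 and 251), while at the left end of chromosome B, YALI0_B00110g and YALI0_B00132g had 0 reads in the parent and 136 and 88, and 62 and 50, in the deletion strain. At the other strain's rate the smallest of these genes would have had 94.2 reads. They were chosen for at least 10 reads in each library of the other strain. A test of low depth against a floor of 3 reads could therefore not fail, and no conclusion is drawn from it. Scatter along the genome is argued against, with exact hypergeometric p-values times 12 arms of 4.466e-11 for E and 7.577e-05 for B. A candidate explanation is that the end of chromosome E from about 4172072 is missing from the DNA of the deletion strain. In this segment 0 genes without a close annotated copy had 3 or more reads in that strain. That count could not decide, because the segment was drawn from YALI0_E34947g, a gene without deletion reads, and YALI0_E35046g was set aside. Its other genes were chosen for having 0 deletion reads or had few or no parent reads, so the count does not favour such a loss. Farther in, such a loss leaves YALI0_E34903g (start 4159769), which fell 7.78-fold with 66 and 39 reads left, and YALI0_E34925g, with 21 and 38 parent reads and 26 and 0 in the deletion strain, unaccounted for, while YALI0_E35046g kept 13.3% of its parent level, in reads that may come from the 5 other tested genes annotated as HSP70. Missing DNA and silenced DNA cannot be told apart from RNA, and whether either followed from the loss of SUR2 or arose separately in these strains was not tested.

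The ERG2-like gene YALI0_B17204g rose 235-fold beside a second gene annotated as ERG2, YALI0_E32065g. Reads moving from the second gene to the first are argued against, because the lowest summed CPM of the pair in the deletion strain was 1.123 times the highest in the parent, and because the first gene gained at least 3.468 times the CPM that the second lost in each table; the latter test was added after the former value was seen. Extra copies of a wider stretch are argued against by the 5 tested genes on each side, whose median log2 fold change was 0.282, although the highest reached 2.36. The genotype, in which the strains differ by both SUR2 and the LEU2 marker and may differ elsewhere, as at the chromosome ends, stays open, as untested. So do copies of the gene alone and the state of the cultures.

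The ribosomal and respiratory lists were lower in the deletion strain, with medians of -1.21, -0.61 and -0.92 for cytosolic ribosomal, mitochondrial ribosomal and oxidative phosphorylation genes, with the preset correlation only (adjusted p = 0.853 for each with an estimated correlation). Gene length or level, as far as broad bins of both match it, is argued against, since each list's median lay below those of all 10000 random lists so matched (percentile 0.0). Levels within a bin were not matched, so a bias of the most abundant genes within their bin stays open. For the cytosolic ribosomal list the matched lists themselves had a median of -0.239. Random members were drawn singly, so those lists do not vary together as genes of 1 list can. Unequal depth, acting through counting error, is argued against by the reads of these genes, since at the smallest library's depth the error of a typical member was at most 0.033 on the log2 scale. Thinned counts moved the medians by at most 0.021. Thinning keeps each gene's share of the counts on average, so at these read numbers a large move was not possible and the result adds nothing. A single library that stands apart stays open: without the gene table's deletion library the medians were -0.88, -0.47 and -0.47, and the excess over the difference between the parent libraries (0.604, 0.503 and 0.194) was as small as -0.035, so such a library and a strain effect cannot be told apart. The genotype and a difference in growth between the cultures stay open, as untested.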
